A study of Mus musculus with 6 samples.

How the data were processed

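Poly(A) RNA from 6 mouse hearts was sequenced, 3 from wild-type mice (Otub1 +/+, called WT here) and 3 from mice with 1 disrupted Otub1 copy (Otub1 +/-, called Het). All 6 mice had received doxorubicin in 6 injections over 2 weeks, per the labels. Each library is 1 mouse, and libraries are named by genotype and replicate number (WT 1 to WT 3, Het 1 to Het 3).

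Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented and reverse-transcribed, and the second strand was marked with dUTP and digested, which makes the libraries stranded. Whether strand was used in quantification is not given in the sources used here. The submitters' processing notes name the mouse build mm10, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2, without saying which step each served. The deposited table holds FPKM, fragments scaled by transcript length and by mapped fragments, for each of the 6 libraries and 14956 genes. The unit was inferred from the deposited values and from StringTie being named, as no header gives it. The table holds no counts. Per the file headers, the authors' p-value, q-value and log2 fold change for the comparison of Het with WT stand beside the FPKM. Recomputing from the deposited table showed that the q-value is the Benjamini-Hochberg adjustment of the p-value over these genes, to within 3.66e-15. The log2 fold change is the log2 ratio of the mean FPKM, with a mean of 0 replaced by 0.0001, to within 4.97e-14. The smallest sum of FPKM over the 6 libraries was 0.502, so genes below a sum near that value were left out before deposit. Of the 14956 gene identifiers, 14596 (97.6%) were found in GENCODE M21, the annotation of GRCm38 (mm10) used here for coordinates, 14223 of them under the same name, and 360 were not found. The authors' annotation is therefore another release than M21, and coordinates below are those of M21.

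Summed FPKM per library was 538779, 581580 and 552726 in WT 1, 2 and 3, and 763010, 570940 and 575129 in Het 1, 2 and 3. FPKM has no fixed sum, so these totals are not depths. Short RNAs in the table carry values that are whole multiples, within 0.0001, of a step that differs between libraries. This held for 12 to 17 of 218 to 278 short RNA values in a library. The inverse of that step put the relative depth of the libraries between 0.696 (Het 3) and 1 (Het 2). The absolute number of reads is unknown, so no counting interval is given, and the error given here is the spread between mice.

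Values were compared on the log2(FPKM + 1) scale, which understates changes of genes near or below 1 FPKM. The 11096 genes with a mean of at least 1 FPKM were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust variance), Het against WT, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A count model had been planned should counts be present. The table holds FPKM, so the limma fit took its place, as the plan foresaw. The median log2 fold change over all tested genes was −0.18, which comes mainly from Het 1. Changes are therefore also given relative to that median. For Otub1 an exact two-sided permutation test was computed, whose smallest possible p with 3 mice against 3 is 0.1. Figures were drawn with matplotlib 3.10.9.

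Before the data were examined, 34 gene lists were fixed that cover pathways of doxorubicin injury, heart metabolism and structure, immune responses and markers of other cell types. The 30 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 30 lists. They were tested again with an estimated correlation and with fry. Unlike camera, which compares a list with all other genes, fry tests a list against no change, so the median shift of −0.18 enters its result. Per library, a list is described by its median log2 difference from the WT mean, relative to the median of all genes. The rule for named genes was fixed at the same time. It takes Otub1, up to 10 called genes per direction whose groups do not overlap, filled to 5 by the smallest unadjusted p, up to 4 members of each list by smallest p, and a panel of 12 genes. Predicted gene names were left out of the rule.

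The gene test was checked on simulated data, with 200 changed genes. With the spread of the WT libraries, over 10871 genes, 95 of 100 genes changed by 1 on the log2 scale and 92 of 100 changed by 2 were recovered. With the spread of all 6 libraries, over 10863 genes, 29 of 100 and 93 of 100 were recovered, and 8 unchanged genes were called. The simulation gave both groups the same spread and drew genes independently. In the data the SD of log2 ratios to the WT mean was 0.140 to 0.148 in WT and 0.326 to 0.771 in Het. The recovered shares therefore need not hold for these hearts.

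Alternatives planned before the data were examined were a pseudocount of 0.1, the replicate number as a block, leaving out each library, other thresholds, camera with an estimated correlation and fry. Alternatives added later were no filter, a stricter filter, median-ratio scaling, scaling to the sum without mitochondrial genes, quantile normalization and library weights. Alternatives that need counts were not run because the table holds no counts. Lists of hepatocyte and of lung epithelial transcripts were written after the data had been seen.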

Results

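Doxorubicin is an anthracycline chemotherapy drug whose use is limited by injury to the heart. OTUB1 is a deubiquitinase of the OTU family, an enzyme that removes ubiquitin from proteins and also blocks some ubiquitin-conjugating enzymes. The comparison asked how the heart transcriptome of doxorubicin-treated mice with 1 disrupted Otub1 copy differed from that of treated wild-type mice. Gene expression was measured by poly(A) RNA sequencing in 3 WT and 3 Het hearts, and 14956 genes were listed in FPKM. All 6 mice had received doxorubicin, so the values describe genotypes under treatment and hold no untreated reference. Read depth is unknown in absolute terms. The relative depth read from the steps in short RNA values lay between 0.696 and 1 of the deepest library.

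Otub1 expression was lower in every Het heart than in every WT heart. Otub1 (ENSMUSG00000024767, chromosome 19, 7198202 to 7206316, minus strand, GRCm38) stood at 15.4, 14.9 and 14.2 FPKM in WT 1, 2 and 3. It stood at 4.83, 6.48 and 6.65 FPKM in Het 1, 2 and 3. The means were 14.8 ± 0.606 FPKM in WT and 5.98 ± 1.00 FPKM in Het (SD, n = 3 each), so Het hearts held 40.4% of the WT mean. The log2 fold change was −1.19 (SE 0.19), or −1.01 relative to all genes. The exact two-sided permutation p was 0.1, the smallest that 3 mice against 3 allow. In limma's test over 11096 genes Otub1 had an unadjusted p of 4.4e-04 and an adjusted p of 0.376, which misses the threshold. The adjusted p was 0.0131 without Het 1, and it lay between 0.00385 and 0.936 over the alternatives. The authors' deposited table lists Otub1 with a log2 fold change of −1.31 and an adjusted p of 1.6e-17. Otub2, the paralog of Otub1, stood at 1.41 ± 0.139 FPKM in WT and 1.38 ± 0.257 FPKM in Het (SD, n = 3 each).

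**Figure D1:**
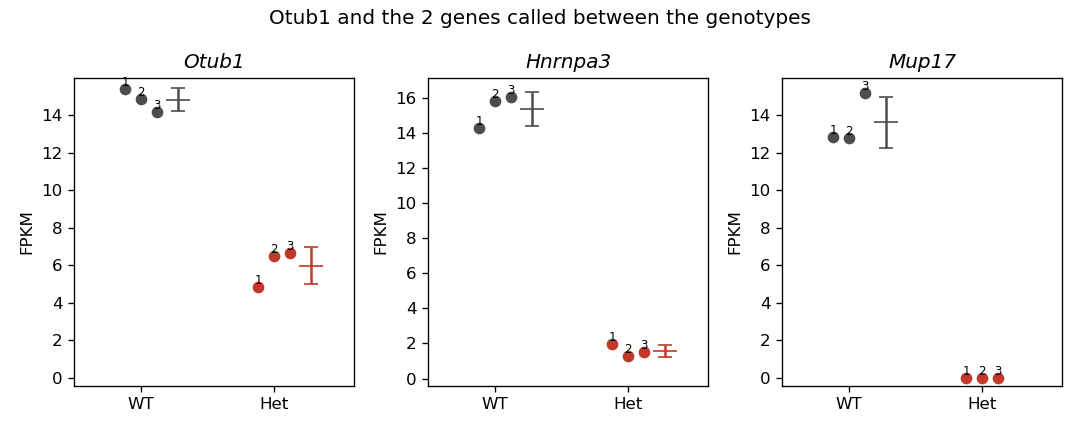
FPKM of Otub1, Hnrnpa3 and Mup17 in each heart, with points numbered by replicate and a bar for the mean with its SD (n = 3), left out where all values are listed at 0. Otub1 lay between 14.2 and 15.4 FPKM in WT and between 4.83 and 6.65 FPKM in Het, and Mup17 was listed at 0 in the 3 Het hearts.

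Besides Otub1, the genes that separated the genotypes most clearly were an RNA-binding protein and transcripts best known from liver, all lower in Het. Hnrnpa3 (chromosome 2, 75659261 to 75669407), which encodes an RNA-binding protein of the hnRNP A/B family, fell from 15.4 ± 0.974 FPKM in WT to 1.57 ± 0.349 FPKM in Het (SD, n = 3 each). Its log2 fold change was −2.68 (SE 0.17) with an adjusted p of 0.00701 in limma's test. Mup17 (chromosome 4, 61591929 to 61595871), a major urinary protein gene made chiefly in liver, stood at 12.8, 12.8 and 15.2 FPKM in the WT hearts. It was listed at 0 in all 3 Het hearts, with an adjusted p of 2.5e-04 in limma's test. Mup17 lies in a cluster of near-identical genes that share reads, so its level is uncertain. Next by unadjusted p among lower genes, with predicted gene names left out, came 3 further liver genes, all short of the threshold. The carboxylesterase Ces3a stood at 2.74, 2.39 and 2.77 FPKM in WT, at 0.484 FPKM in Het 2 and at 0 in Het 1 and Het 3. Mup7 stood at 2.71, 5.21 and 3.00 FPKM in WT and at 0.292 FPKM in Het 2. Mup2 stood at 2.68, 2.01 and 2.82 FPKM in WT and at 0.486 FPKM in Het 2, and both were listed at 0 in Het 1 and Het 3. Their adjusted p values were 0.166, 0.166 and 0.235. Without Het 2, Ces3a and Mup2 passed (adjusted p 0.0165 and 0.0247).

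No gene was called higher in Het in limma's test with equal library weights. The 5 genes with the smallest unadjusted p in that direction, with predicted gene names left out, all missed the threshold. Of these, 3 were neighbouring mitochondrial genes for the tRNAs that carry isoleucine, glutamine and methionine. They lie directly before mt-Nd2, and the libraries were selected for poly(A) RNA. Whether the values reflect mature tRNA was not tested. mt-Tm had 1716 ± 157 FPKM in WT and 6809 ± 2506 FPKM in Het, and mt-Tq had 1026 ± 52.4 and 3701 ± 1026 FPKM (SD, n = 3 each). mt-Ti had 489.8 ± 50.7 FPKM in WT and 1279 ± 118 FPKM in Het (SD, n = 3 each). Their adjusted p values in limma's test were 0.554, 0.376 and 0.435. Without Het 1 all 3 passed as higher, at 0.00107, 0.00107 and 0.0144. With library weights they passed at 2.2e-04, 2.2e-04 and 0.00385. Those weights gave Het 1 only 0.0486 against 1.51 to 2.55 for the others, so this setting nearly repeats leaving out Het 1. The authors' deposited table lists mt-Tm, mt-Tq and mt-Ti as higher, with adjusted p values of 3.4e-18, 9.9e-36 and 3.2e-06. The ribosomal protein pseudogene Rps26-ps1 had 0.558 ± 0.265 FPKM in WT and 2.05 ± 0.694 FPKM in Het. Themis2, a signalling adaptor of B cells and macrophages, had 0.778 ± 0.164 and 1.66 ± 0.333 FPKM (SD, n = 3 each). Both had an adjusted p of 0.753, and Rps26-ps1 passed with library weights (adjusted p 0.0286).

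In all, limma called 2 of 11096 genes at an adjusted p under 0.05, 0 higher and 2 lower in Het, and 431 genes had an unadjusted p under 0.05, 89 higher and 342 lower. The groups did not overlap for 1930 genes (17.4%), where chance gives 10%. Of these 1727 were lower and 203 higher in Het, on a scale on which the median gene was at −0.18. The predominance of lower genes depends on scaling. At an unadjusted p under 0.05, 181 genes were higher and 212 lower with median-ratio scaling, and 187 and 229 with quantile normalization. Scaled without mitochondrial genes, 228 were higher and 176 lower. Leaving out single libraries moved the count. It was 1 without WT 1, WT 2 or WT 3, each time Mup17. Without Het 1 it was 8 (3 higher, 5 lower), and without Het 2 it was 25, all lower and mostly liver genes such as Alb and Fabp1. Without Het 3 it was 38 (36 higher, 2 lower), with 22 of the interferon response genes among them. Mup17 kept its call in all 14 alternatives, and Hnrnpa3 lost it in 7 of them, with an adjusted p between 7.1e-06 and 0.168. The authors' deposited table holds 152 genes with an adjusted p under 0.05, 116 higher and 36 lower in Het, over all 14956 genes. Of these, 102 have a mean of at least 1 FPKM, as the genes tested here do. The 152 include 9 of 20 lung epithelial and 4 of 32 hepatocyte transcripts of the lists written after the data were seen. The lists are short and the other calls were not sorted by organ, so these counts can understate such genes. Mup17, Mup9, Mup11 and Mup18, for example, are among the 152 but not in the hepatocyte list.

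The hearts differed in ways that did not follow genotype alone. Het 1 correlated with the other libraries at 0.844 to 0.887 across genes, while the other 5 libraries had a highest correlation with another of 0.970 to 0.987. Mitochondrial transcripts made up 65.0% of the summed FPKM in Het 1 and 51.5% to 56.1% in the others. Transcripts typical of hepatocytes, the main cells of liver, were present in all WT hearts. Over 32 such genes their summed FPKM was 224, 208 and 299.9 in WT 1, 2 and 3, and 4.42, 74.2 and 18.6 in Het 1, 2 and 3. Of the sum of 18.6 in Het 3, Hp alone made up 15.4, so that sum does not describe the other genes. Albumin (Alb) stood at 44.9, 35.3 and 57.2 FPKM in WT and at 0.766, 16.7 and 0.296 FPKM in Het 1, 2 and 3. Transcripts typical of lung epithelium were high in Het 3, with a summed FPKM over 20 genes of 875 against 0.616 to 1.16 in the WT hearts, 0.726 in Het 2 and a similarly low level in Het 1. Scgb1a1, a secretory protein of airway club cells, stood at 476 FPKM in Het 3 and was listed at 0 elsewhere. Sftpc, a surfactant protein of alveolar cells, stood at 261 FPKM in Het 3 and at most at 0.109 FPKM elsewhere.

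**Figure D2:**
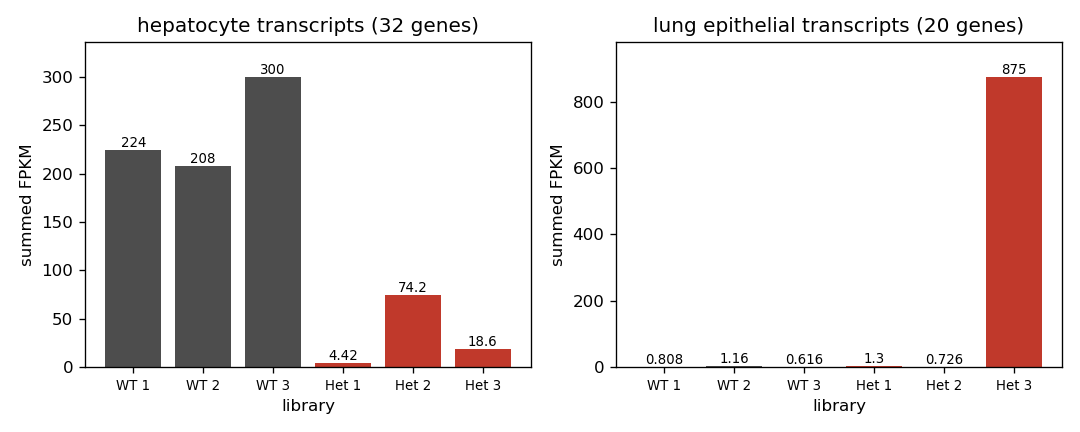
Summed FPKM of 32 hepatocyte transcripts and of 20 lung epithelial transcripts in each heart, with WT in grey and Het in red. The hepatocyte sum was 208 to 299.9 in WT and 4.42 to 74.2 in Het, and the lung sum was 875 in Het 3 and 0.616 to 1.16 in WT. In Het 3, Hp alone made up 15.4 of the hepatocyte sum of 18.6.

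Of the 30 tested gene lists, 5 passed the set test, 4 higher and 1 lower in Het relative to all genes, and 0 passed with an estimated correlation. The genes of the interferon response, the antiviral programme switched on by interferons, moved furthest. Their 37 tested members rose as a set (camera adjusted p 3.7e-52, adjusted p = 0.918 with an estimated correlation), with a median log2 fold change of 1.56, or 1.74 relative to all genes. All 37 lay above the median gene and 13 were higher in every Het than in every WT heart, where chance gives 5% in that direction. None passed over all genes and 0 passed adjusted over the list alone, while 21 had an unadjusted p under 0.05 in limma's test. The response was carried by Het 1 and Het 2. The median of the list relative to all genes was 2.62 in Het 1, 2.20 in Het 2 and 0.11 in Het 3, against −0.09, 0.13 and −0.01 in WT 1, 2 and 3. Blood and erythroid genes had the same order over the Het hearts, with medians of 2.28, 0.68 and −0.65.

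**Figure D3:**
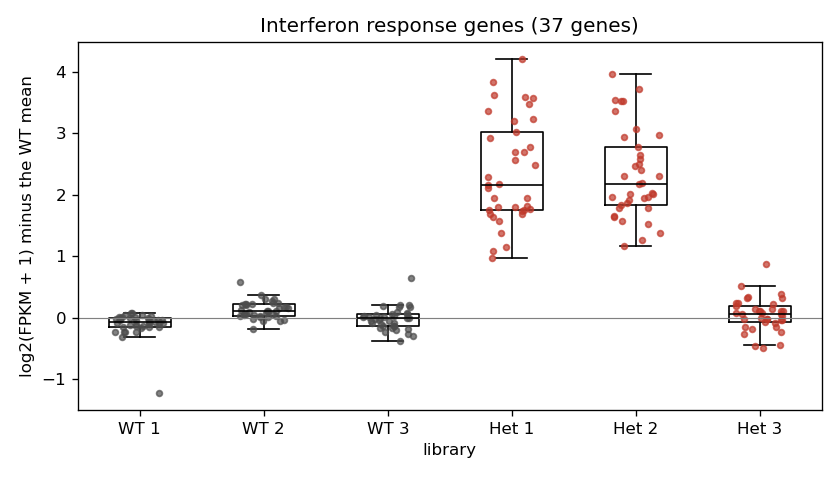
Each point is 1 of 37 interferon response genes, as log2(FPKM + 1) minus its WT mean, per heart, with boxes for the median and middle quartiles. All genes lie above 0 in Het 1 and Het 2, while in Het 3 and in each WT heart they lie on both sides of 0.

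Irf7, a transcription factor that amplifies interferon production, stood at 72.7 FPKM in Het 1, 40.01 FPKM in Het 2 and 2.93 FPKM in Het 3, and at 2.40, 3.07 and 3.58 FPKM in WT. Ifit3, an antiviral effector, stood at 52.2, 56.9 and 4.73 FPKM in Het 1, 2 and 3 and at 2.55 to 4.07 FPKM in WT. The ubiquitin-like modifier Isg15 stood at 33.2, 19.8 and 1.44 FPKM in Het and at 2.23 to 2.40 FPKM in WT. The 4 members with the smallest p were Rsad2, Psmb9, Ifit2 and Ifi44. Rsad2 (viperin) had 2.21 ± 0.274 FPKM in WT and 8.21 ± 4.10 FPKM in Het, and Psmb9, a subunit of the immunoproteasome, had 0.833 ± 0.0424 and 2.53 ± 1.11 FPKM (SD, n = 3 each). Ifit2 had 2.11 ± 1.71 and 14.3 ± 9.21 FPKM, and Ifi44 had 0.515 ± 0.0508 and 3.83 ± 2.64 FPKM (SD, n = 3 each). The adjusted p of each was 0.753 in limma's test. Without Het 3, 22 members of the list passed over all genes and 37 adjusted over the list alone. With Het 3 left in and any other library left out, 0 passed. Of 39 members listed in the authors' deposited table, 28 have an adjusted p under 0.05 there.

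Markers of macrophages rose as a set, by less (22 tested members, camera adjusted p 9.8e-07, median 0.47 relative to all genes, 20 members above the median gene). Its adjusted p was 0.918 with an estimated correlation. No member passed over all genes or adjusted over the list alone. The median was 0.59 in Het 3, the heart with lung transcripts, and 0.11 and 0.23 in Het 1 and Het 2. Lyz2, a lysozyme of macrophages and alveolar cells, stood at 168 FPKM in Het 3 and at 44.6 to 58.9 FPKM in the other hearts. The complement gene C1qa went the other way, at 39.0 and 38.8 FPKM in Het 1 and Het 2, 26.4 FPKM in Het 3 and 23.3 to 29.3 FPKM in WT. Csf1r, the receptor for macrophage colony-stimulating factor, had 3.86 ± 0.227 FPKM in WT and 5.39 ± 1.59 FPKM in Het (SD, n = 3 each). Of the lymphocyte, neutrophil and epicardial lists 3, 2 and 3 members reached the filter, too few for a set test. Among them the immunoglobulin chain gene Igkc stood at 5.06 FPKM in Het 3 and at 0 to 1.37 FPKM elsewhere. With no filter the lymphocyte list could be tested and passed as higher. Of its 9 members listed, only 3 had a mean of at least 1 FPKM.

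Blood and erythroid genes rose as a set (9 tested members, camera adjusted p 1.7e-05, median 0.69 relative to all genes, 9 members above the median gene). The adjusted p was 0.984 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The rise lay in Het 1 and Het 2, with medians of 2.28 and 0.68 against −0.65 in Het 3, and the adjusted p was 0.537 without Het 1 and 0.375 with library weights. The haemoglobin genes Hbb-bs and Hba-a1 stood at 2148 and 1545 FPKM in Het 1, 1083 and 582 FPKM in Het 2, and 314 and 168 FPKM in Het 3. In WT they stood at 409 to 598 and 244 to 339 FPKM. Endothelial markers also passed as a set (24 tested members, camera adjusted p 0.0273, median 0.19 relative to all genes, 18 members above the median gene). Their adjusted p was 0.984 with an estimated correlation, and 0 members passed by either count. Without WT 1, WT 3, Het 1 or Het 3 it was 0.0933, 0.0759, 0.652 and 0.119. With no filter it was 0.0668, and with library weights it was 0.951. The list's median was 0.70 in Het 1, −0.20 in Het 2 and 0.08 in Het 3. The members did not move alike in Het 1. Egfl7, secreted by endothelial cells, stood at 58.7 FPKM in Het 1 and at 17.8 to 30.4 FPKM in the other hearts. Kdr and Pecam1 were lowest in Het 1, at 10.2 and 18.7 FPKM, against 17.0 to 22.9 and 22.7 to 30.7 FPKM in the other hearts.

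The immediate early genes, transcription factors and regulators induced within minutes of a stimulus, fell as a set in Het (19 tested members, camera adjusted p 0.0273, median −0.11 relative to all genes, 16 members below the median gene), with an adjusted p of 0.984 with an estimated correlation. No member passed over all genes and 2 passed adjusted over the list alone, Maff and Klf4. Maff, a small Maf transcription factor, had 6.46 ± 0.827 FPKM in WT and 3.42 ± 0.226 FPKM in Het, and Klf4 had 26.7 ± 1.602 and 14.9 ± 1.73 FPKM (SD, n = 3 each). Nr4a3 had 2.50 ± 0.418 and 0.969 ± 0.857 FPKM, and the stress-induced factor Atf3 had 4.76 ± 0.509 and 2.76 ± 1.05 FPKM (SD, n = 3 each). The median was −0.26 in Het 1, −0.43 in Het 2 and 0.03 in Het 3. Without Het 2 the adjusted p was 0.583, and without WT 3 it was 0.129.

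**Figure D4:**
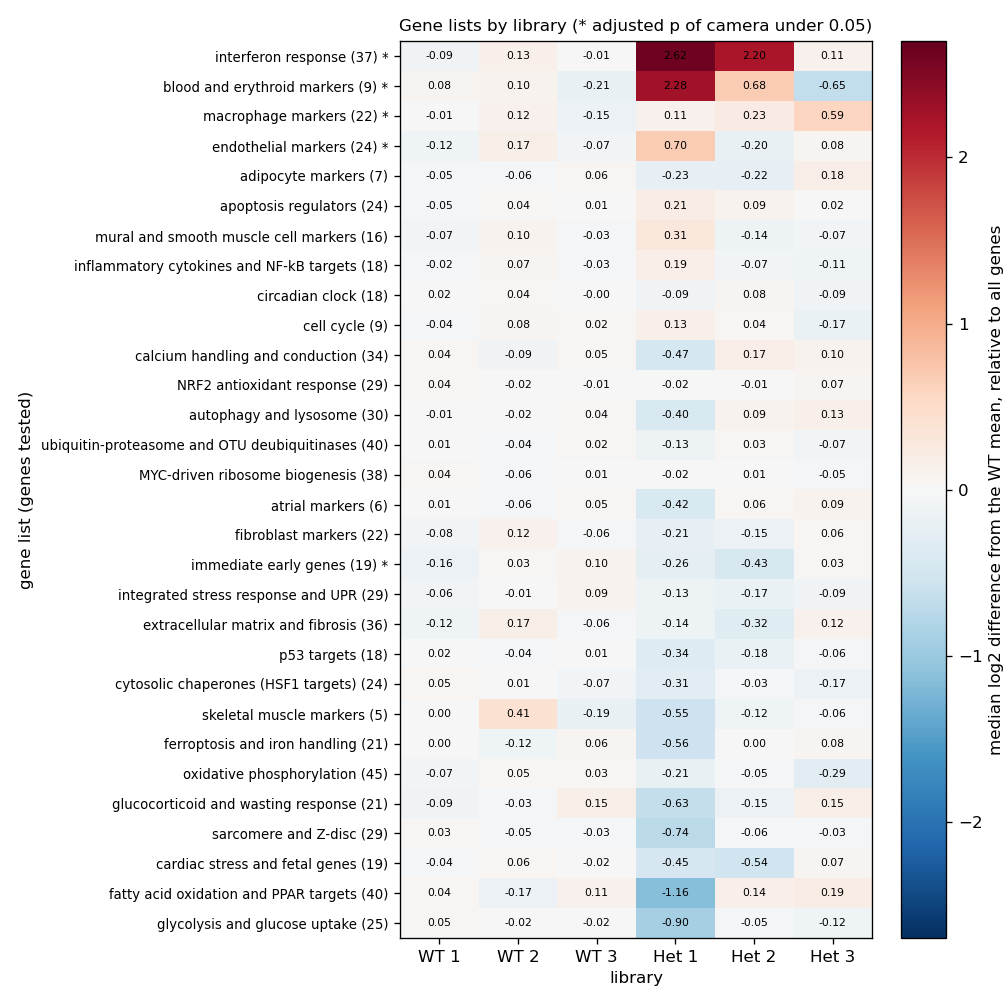
Median log2 difference from the WT mean of each tested gene list in each heart, relative to all genes, with the number of tested genes in brackets and a star where camera's adjusted p was under 0.05. The interferon list reaches 2.62 in Het 1 and 2.20 in Het 2, and fatty acid oxidation genes reach −1.16 in Het 1.

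Lists tied to doxorubicin injury and to the known partners of OTUB1 did not pass. The targets of p53, the DNA damage factor, had a camera adjusted p of 0.27, and 0 of 18 tested members passed by either count. Cdkn1a, the cell cycle inhibitor p21, was lower in every Het heart, at 15.5 ± 1.97 FPKM in WT and 7.70 ± 1.63 FPKM in Het (SD, n = 3 each, adjusted p 0.753 in limma's test). The authors' deposited table lists Cdkn1a with a log2 fold change of −1.01 and an adjusted p of 0.0156. Phlda3, another p53 target, had 7.52 ± 0.847 and 5.11 ± 0.769 FPKM. Trp53 itself had 3.94 ± 0.586 and 3.46 ± 0.209 FPKM, and Mdm2, its ubiquitin ligase, had 9.06 ± 0.652 and 8.50 ± 1.22 FPKM (SD, n = 3 each). Without Het 1 the p53 list passed as lower. Apoptosis regulators (camera adjusted p 0.425) included Bcl2l1, a survival factor, at 13.8 ± 0.666 and 9.44 ± 1.04 FPKM (SD, n = 3 each). Ribosome biogenesis genes driven by MYC had an adjusted p of 0.0931, and passed as lower with no filter (adjusted p 0.0432). Myc stood at 0.838 ± 0.175 and 1.07 ± 0.198 FPKM (SD, n = 3 each), a mean over the 6 hearts below the filter. The integrated stress and unfolded protein responses had an adjusted p of 0.098, and passed as lower without WT 1 (adjusted p 0.0201). They also passed as lower with no filter (0.0482), the stricter filter (0.0400) and scaling without mitochondrial genes (0.0428). Of 29 tested members 7 were lower at an unadjusted p under 0.05 in limma's test. Of these Pdia6, a chaperone of the endoplasmic reticulum, had 22.7 ± 5.30 and 12.1 ± 3.31 FPKM, and Manf had 7.00 ± 1.66 and 4.28 ± 0.347 FPKM (SD, n = 3 each). Glucocorticoid and wasting genes had an adjusted p of 0.0931 and passed as lower without WT 1 (adjusted p 0.0201) or Het 3 (adjusted p 0.00756). Among them the kinase Sgk1 was lower in every Het heart, at 25.4 ± 1.22 and 15.0 ± 1.71 FPKM (SD, n = 3 each).

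Genes of cardiac stress and of the fetal programme missed the threshold (camera adjusted p 0.0931, 19 tested members, 13 below the median gene), and passed as lower without WT 1, Het 1 or Het 3. Myh7, the slow myosin heavy chain re-expressed under strain, had 191 ± 21.3 FPKM in WT and 97.3 ± 9.59 FPKM in Het (SD, n = 3 each, adjusted p 0.753 in limma's test). All 3 Het hearts lay below all 3 WT hearts, and Myh7 passed as lower with library weights (adjusted p 0.0388). The natriuretic peptide genes varied within groups, with Nppa at 238 ± 136 and 128 ± 90.7 FPKM and Nppb at 46.3 ± 11.8 and 25.3 ± 19.6 FPKM (SD, n = 3 each). Myh6, the adult myosin, had 4078 ± 377 and 3523 ± 834 FPKM (SD, n = 3 each). Sarcomere and Z-disc genes had an adjusted p of 0.0931 and a median of −0.74 in Het 1, against −0.06 and −0.03 in Het 2 and Het 3. Glycolysis genes (adjusted p 0.0691) had −0.90 in Het 1 and fatty acid oxidation genes (adjusted p 0.412) −1.16 in Het 1, against −0.12 to 0.19 in the other Het hearts. Ppargc1a, a coactivator that drives mitochondrial gene expression, had 29.8 ± 13.5 FPKM in WT and 13.4 ± 9.42 FPKM in Het (SD, n = 3 each). Calcium handling genes (adjusted p 0.558) and oxidative phosphorylation genes (adjusted p 0.129) also missed the threshold. The direction of the fatty acid oxidation list depends on Het 1. It passed as higher without Het 1 (adjusted p 5.8e-04) and as lower without Het 3 (adjusted p 0.00967). Without Het 1 the calcium handling list also passed as higher (adjusted p 0.00218) and the oxidative phosphorylation list as lower (adjusted p 1.8e-04). Glycolysis genes passed as lower without Het 2 (adjusted p 0.0301) or Het 3 (adjusted p 0.0408). With median-ratio scaling the sarcomere, stress, oxidative phosphorylation, fatty acid oxidation, glycolysis and glucocorticoid lists passed as lower.

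The remaining lists missed the threshold, and some passed under other settings. The NRF2 antioxidant list had an adjusted p of 0.989, and Hmox1, a haem-degrading enzyme of that response, had 6.57 ± 3.55 and 4.17 ± 1.93 FPKM (SD, n = 3 each). The ferroptosis and iron list had an adjusted p of 0.558. Its guard enzyme Gpx4 had 138 ± 9.99 and 115 ± 13.0 FPKM, and the transferrin receptor Tfrc had 21.4 ± 5.44 and 7.39 ± 7.06 FPKM (SD, n = 3 each). Extracellular matrix genes had an adjusted p of 0.0931 and fibroblast markers 0.237. The matrix list passed as lower without WT 1 (adjusted p 0.00622) or Het 3 (adjusted p 0.0011), and with no filter (adjusted p 0.0432). Col1a1 had 11.8 ± 1.24 and 8.88 ± 3.07 FPKM and Col3a1 14.3 ± 2.20 and 11.1 ± 3.38 FPKM (SD, n = 3 each). The adjusted p was 0.961 for inflammatory cytokines and NF-kB targets, 0.237 for cytosolic chaperones, 0.961 for ubiquitin-proteasome genes and 0.802 for autophagy genes, which passed as higher without Het 1 (adjusted p 0.00218) and with library weights (adjusted p 0.0169). It was 0.802 for mural cell, 0.877 for atrial, 0.991 for adipocyte and 0.658 for skeletal muscle markers. It was 0.658 for circadian clock and 0.802 for cell cycle genes. In the adipocyte list 1 of 7 tested members passed adjusted over the list alone. This was Car3, a carbonic anhydrase also made in liver and muscle, at 3.91 ± 1.04 and 0.732 ± 0.535 FPKM (SD, n = 3 each). All 6 hearts expressed the Y-linked genes Ddx3y (9.89 to 12.9 FPKM) and Eif2s3y (11.6 to 14.4 FPKM), so all 6 mice were male by this measure.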

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

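The added filters, scalings and library weights below were chosen after the data were seen, and the other settings were planned. Otub1 stayed lower in Het under all 14 settings. It passed the adjusted threshold with library weights, at −1.07, and without Het 1, and the values with single libraries left out ranged from −1.26 to −1.06. The number of called genes was 2 with a pseudocount of 0.1, with no filter and with the stricter filter. It was 1 with median-ratio scaling, scaling without mitochondrial genes and quantile normalization, 22 with library weights (4 higher, 18 lower), and 112 at an unadjusted p under 0.05 with an absolute log2 fold change of at least 1 (48 higher, 64 lower). With single libraries left out it ranged from 1 to 38, and the cause was not tested beyond the smaller number of samples. Library weights gave Het 1 a weight of 0.0486 against 1.51 to 2.55 for the others. The number of passing lists was 11 with no filter, 11 with median-ratio scaling, 12 with scaling without mitochondrial genes and 9 with library weights, and it ranged from 3 to 9 with single libraries left out. It was 0 with an estimated correlation and 0 with fry. With library weights the fatty acid oxidation, calcium handling and autophagy lists passed as higher, and with median-ratio scaling fatty acid oxidation passed as lower. With no filter the MYC, cardiac stress, glycolysis, integrated stress, matrix and glucocorticoid lists passed as lower, and the lymphocyte list passed as higher. The interferon and macrophage lists kept their call in 14 of 16 settings and lost it with an estimated correlation (adjusted p 0.918 for both) and with fry (0.439 and 0.497). With single libraries left out the adjusted p of the endothelial list ranged from 1.6e-04 (without Het 2) to 0.652. The list turned lower without Het 1 (adjusted p 0.652), and the cause was not tested. With library weights its call was lost (adjusted p 0.951), as was that of the blood list (adjusted p 0.375). With fry, which tests against no change and not against other genes, its adjusted p was 0.986, and its median without the shift was 0.01. Of 143 other named genes 13 gained and 1 lost a call under some setting. With library weights Klf4, Sgk1, Myh7, Car3, Mup7, Mup2 and Ces3a passed as lower. Unscaled values put the median gene at −0.18, and the 3 scalings moved it to between −0.01 and 0.02. With the replicate block 1 gene and 5 lists passed, and 27 of 37 interferon response genes passed adjusted over the list alone. The correlations of same-numbered deviations were −0.20, −0.43 and 0.21, so the numbers were not taken to pair the mice. Alternatives that need counts were not run. Depth is unknown, so what it limits was not assessed.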

Other observations

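The tests of other organs, of macrophages, of scaling and of cell types were chosen after the results were seen, as was the split of a planned test of length and GC into a test of each, while the list counts over other splits were planned before.

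Beyond the fixed lists, the pathway annotation in the table was tested with camera, and 21 of 302 pathways passed, 16 higher and 5 lower in Het. None passed with an estimated correlation, where the smallest adjusted p was 0.563. The 4 leading pathways share 13 genes, of which 12 are genes of the major histocompatibility complex, which display peptides to T cells. Their class I genes were highest in Het 1 and Het 2, and some also stood above all WT hearts in Het 3. The median of the 12 genes relative to all genes was 1.33, 0.88 and 0.25 in Het 1, 2 and 3 and at most 0.16 in WT, and 5 were higher in every Het than in every WT heart. H2-Q7 stood at 4.15, 4.52 and 2.54 FPKM in Het and at 1.76 to 1.86 FPKM in WT. H2-T23 stood at 19.6, 20.4 and 7.68 FPKM in Het 1, 2 and 3 and at 5.46 to 8.08 FPKM in WT, and H2-Q4 at 34.4, 26.7 and 13.99 FPKM in Het and at 11.3 to 14.2 FPKM in WT. The class II genes went another way. H2-Ab1 stood at 16.3 FPKM and H2-Eb1 at 20.5 FPKM in Het 3, the heart with lung transcripts, and at 3.42 to 6.41 and 4.06 to 9.86 FPKM elsewhere. The GTPase genes Gbp4 and Tgtp1, picked after the data were seen, did not pass (adjusted p 0.753 each in limma's test). Gbp4 stood at 20.5, 17.3 and 2.68 FPKM in Het 1, 2 and 3 and at 1.43 to 2.35 FPKM in WT, and Tgtp1 at 20.6, 24.9 and 1.86 FPKM in Het and at 1.70 to 2.74 FPKM in WT. Ribosome genes were lower as a set (131 genes, adjusted p 0.00555, adjusted p = 0.9997 with an estimated correlation), with medians of −0.20 in Het 2, −0.41 in Het 3 and 0.27 in Het 1. Rps13 stood at 9.64, 3.42 and 5.13 FPKM in Het and at 11.8 to 15.7 FPKM in WT.

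Interferon response genes were high in Het 1 and Het 2 and near the WT level in Het 3. Scaling by the mitochondrial share is argued against, because 1 factor moves all genes alike, while the list's median stood at least 2.20 above that of all genes in these 2 hearts. More macrophages of the kind already present are argued against as well, since the highest median of their markers in these 2 hearts was 0.23, against at least 2.20 for the interferon genes. Blood and erythroid genes had the same order over the Het hearts (2.28, 0.68 and −0.65), and blood cells as a source, a change of state within cells and an infection or other exposure of 2 mice stay open and were not tested. The Otub1 genotype may contribute, but the lowest median in a Het heart was 0.11, inside the WT range, and with 1 such heart of 3 this cannot be told apart from a difference between mice.

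Liver transcripts in the WT hearts and lung transcripts in Het 3 may come from RNA of other organs carried into the samples. Of the 28 hepatocyte transcripts that the authors' deposited table does not call, 89.3% were lower in all Het than in all WT hearts. Chance gives 5% for a single gene, and 1727 of all 11096 tested genes were lower in this way. The liver and lung lists were written after the data were seen and their members are not independent, so these shares only describe the pattern. In Het 2 the hepatocyte transcripts stood at a median of 32.7% of the WT mean, with middle quartiles of 27.2% and 35.7%, but Mup7, Mup20, Mup2 and Ces3a stood lower, and Mup17 was listed at 0. Of the 32 listed, 29 were lower in all Het than in all WT hearts. In Het 3 Ahsg and Alb, for example, were below WT, at 1.52 and 0.296 FPKM. Hp was the only listed gene above WT there, at 15.4 FPKM against 5.51 to 7.66 FPKM in WT. Het 3 is also the heart with lung transcripts, and the source of its Hp was not tested. All 11 lung transcripts not called in the authors' deposited table (100%) were highest in Het 3. A genotype effect on liver-type transcripts within heart cells was not tested, and the way such RNA could enter the libraries stays open.

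Het 1 stood apart from the other hearts. A single scaling factor, as the higher mitochondrial share would give, is argued against by the spread over nuclear genes, whose log2 ratios to the WT mean had an SD of 0.77 in Het 1 and at most 0.35 in Het 2 and Het 3. Transcript length bias is argued against, since its absolute Spearman rho across genes was 0.0344 in Het 1 and up to 0.295 in the others, while GC bias stays open (0.143 in Het 1, at most 0.107 in the others). A lower share of cardiomyocytes was not decided. Endothelial and fibroblast markers moved apart in Het 1 by 0.91 (permutation p 2.5e-04, adjusted over 6 pairs of lists 0.0015). That permutation shuffled genes within 1 heart as if independent, so its p does not measure the spread between mice. A stronger injury of this mouse, RNA quality and tissue sampling stay open and were not tested.

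The real split of the 6 hearts called 2 genes and the highest of the other splits called 1, so 1 of 10 splits gave as many, counting the real one. For lists the real split gave 5 and the highest other gave 9, and 9 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached, so chance can be neither excluded nor assessed further here. Some splits that group hearts across genotypes passed more lists than the real one, and the cause was not tested.

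The 2 overlapping gene models of Nnt, the mitochondrial transhydrogenase that carries a deletion in the C57BL/6J strain, swung between hearts. Model ENSMUSG00000025453 stood at 39.3, 4.82 and 6.57 FPKM in WT 1, 2 and 3 and at 6.13, 38.5 and 36.6 FPKM in Het 1, 2 and 3. Model ENSMUSG00000116207 stood at 38.2, 90.1 and 112.7 FPKM in WT and at 10.2, 45.2 and 39.1 FPKM in Het. The mitochondrial genes mt-Ti (3706 to 3774), mt-Tq (3772 to 3842) and mt-Tm (3845 to 3913) lie directly before mt-Nd2 (3914 to 4951), which had 16604 ± 708 FPKM in WT and 23738 ± 3035 FPKM in Het (SD, n = 3 each). Rpl37a stood at 6.09, 7.02 and 7.26 FPKM in WT, at 10.7 FPKM in Het 1 and at 2.22 and 2.03 FPKM in Het 2 and Het 3.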
